A study of Mus musculus with 24 samples.

How the data were processed

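Fragments of ileum, the last part of the small intestine, were taken from wild-type male C57BL/6J mice starved for 4 h, kept in culture medium for 8 h with an additive, and profiled by QuantSeq, a 3' tag method that reads each mRNA near its polyadenylated end. Per the labels' protocols, total RNA was isolated with TRIzol and a column kit with DNase treatment, and 100 ng went into each library. The 24 libraries form 6 groups of 4: the solvent DMSO, tauro-conjugated chenodeoxycholic acid (tCDCA), and extracts from wild-type (WT) or Asbt-/- donor mice in the forms CME(-) and CME(+). Asbt is the ileal bile acid uptake carrier encoded by Slc10a2, and the genotype is that of the extract donor. The treated tissue is wild-type in every library, so there was no deleted gene to check. CME is not spelled out in the labels. CME(+) was taken as the bile acid depleted form, because the treatment text speaks of extracts with or without depletion and a concentration of 200 µM is given for CME(-) and tCDCA replicates 2 to 4, not for CME(+). The labels of Asbt-/- CME(-) replicates 2 and 3 and of WT CME(+) replicate 2 have CAM in place of CME, and their titles set the group.

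The authors deposited 1 table of whole-number counts per gene for all libraries, not normalized. Per the submitters' processing notes, FastQC, cutadapt, HISAT2 and Picard were used with the mouse build GRCm39, and no versions were recorded. The counting tool, its strand setting and the annotation are not given in the sources used here. The table holds 57126 gene identifiers. Symbols came from an annotation of an older build (GENCODE M21, GRCm38), so no coordinates were used. It named 51884 identifiers, which held 88.4% of the counts. Genes that belong to families of near-identical copies (defensins, Sprr2, Ces2, Cyp3a, Reg3, antibody and haemoglobin genes, Hspa1a and Hspa1b) are uncertain, because shared reads could have been divided between copies. Genes that overlap on opposite strands are uncertain too.

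Column names carry 2 prefixes, taken here as 2 sequencing runs. The prefixes alone do not tell whether the cultures were separate too. Replicate 1 of each group came from the first run and replicates 2 to 4 from the second. The submitters' labels mark 3 libraries as removed, and these stayed out of the comparisons: DMSO replicate 1 for another DMSO concentration (0.5% against 0.6%), and Asbt-/- CME(-) replicate 3 and WT CME(+) replicate 2 for poor mapping. The 21 libraries used were 3 for DMSO, 4 for tCDCA, 4 for WT CME(-), 3 for WT CME(+), 3 for Asbt-/- CME(-) and 4 for Asbt-/- CME(+). The DMSO group has no used first-run library, so the run effect in comparisons with DMSO was estimated from the other groups. Totals ran from 2.76 to 5.6 M counts per used library. Mitochondrial rRNA held 6.78 to 8.29% of the counts in the 6 first-run libraries and 5.29 to 34.6% in the 18 of the second run. Without this rRNA and 1 abundant identifier with no symbol (ENSMUSG00000119584, 3.21 to 18.63% of counts over the 24 libraries), 1.63 to 4.99 M counts per used library were left. Replicates correlated at r = 0.861 to 0.954 across genes, and no pair differed by as little as sampling noise (lowest chi-square per degree of freedom 5.7).

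Counts were tested in R 4.3.3 with edgeR 4.0.16: low counts were filtered with filterByExpr, libraries scaled by TMM, and 1 robust quasi-likelihood model with a term for group and a term for run was fitted to all 21 libraries. The 12 comparisons were contrasts of this model, 1 of them the difference between the extract contrasts of both donors. Within each, p-values of the 13125 genes tested were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.266. About 656 genes per comparison would have an unadjusted p under 0.05 by chance. Fold changes are log2 with standard error (SE), intervals are 95%, and tests are two-sided. Levels are CPM after TMM scaling, given as mean and SD of the used second-run libraries, with the first-run library beside them. Intervals for a single library are exact Poisson intervals and cover counting error only.

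Comparisons, tests, the main alternatives, 38 gene lists with 512 named genes and the rule for naming genes were set before the data were examined. The rule named, per comparison, 6 genes of the FXR list (Fgf15, Fabp6, Slc51a, Slc51b, Nr0b2, Slc10a2); the 10 called genes with the largest change in each direction that had a proper symbol and a mean log2 CPM of at least 3; and up to 4 called members with the smallest p of each list called by camera and of each list with 3 or more called members. Where nothing was called, it named the 5 such genes with the smallest p. The text was allowed to drop part of the last 2 kinds for the secondary comparisons. Some genes that the rule names are not reported here. Lists were tested with camera (limma 3.58.1, voom values, preset correlation 0.01), adjusted over the lists of a comparison. Beside it stood camera with a correlation estimated from the data, and fry, which tests whether the genes of a list move on balance in 1 direction. A list needed 3 or more tested members.

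Tested on simulated counts with 200 genes changed by known folds, the model recovered 6%, 38.5% and 73.8% of genes changed 1.5-, 2- and 4-fold between tCDCA and DMSO, with 4 false calls among 12826 genes. Between WT CME(-) and CME(+) it recovered 6.2%, 20.9% and 61.9% (2 false calls among 12769 genes), between Asbt-/- CME(-) and CME(+) 3.1%, 30.3% and 76.6% (4 among 12840), and between the CME(-) extracts of both donors 1.5%, 25.8% and 71.9% (3 among 12751).

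Per the labels, replicates 2 to 4 of the CME(-) and CME(+) groups of a donor genotype share the donor animal of the extract. Those numbers therefore pair the extracts, and values with the extract donor as a block are given where they differ. That block was the replicate number in the paired groups alone, and it also paired replicate 1, for which the labels give no donor. Among the used libraries the labelled pairs were replicates 3 and 4 for WT and 2 and 4 for Asbt-/- donors. Deviations of same-numbered second-run libraries from their group means correlated at 0.05 and 0.1 for WT and 0.01 and -0.01 for Asbt-/-. Between other groups the numbers mark only the run. Alternatives covered another scaling (RLE), no scaling factors, no count filter, DESeq2 1.42.0, no run term, a replicate block, only the compared groups, all 24 libraries, the second run alone, and each library left out in turn. After the data had been examined, 3 more were added: the abundant rRNA and the unnamed identifier left out, DMSO replicate 1 added, and tCDCA replicate 3 and DMSO replicate 3 both left out. Comparisons of tCDCA with the CME(+) groups and a division of the DMSO libraries between contrasts were also added then.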

Results

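Ileal fragments of wild-type mice were exposed for 8 h to DMSO, to tCDCA, or to extracts of WT or Asbt-/- mice with bile acids, CME(-), or taken as depleted of them, CME(+). Chenodeoxycholic acid and its taurine conjugate are ligands of FXR, the nuclear receptor by which ileal cells sense bile acids, and Fgf15, a hormone gene of the ileum, is one of its best known targets. The stated aim of the series was to look at how endogenous bile acids regulate genes. Gene counts of 21 libraries, 3 or 4 per group and 2.76 to 5.6 M counts each, were compared. Nothing in the labels says whether the fragments of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

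In tCDCA-treated fragments Fgf15 (ENSMUSG00000031073) was at 232 ± 51.3 CPM (SD, n = 3 second-run libraries), against 7.03 ± 1.01 (n = 3) with DMSO. It rose by 4.98 ± 0.38 log2 units (SE), 31.6-fold, with an edgeR adjusted p of 2.89e-07. Slc10a2 (ENSMUSG00000023073), which encodes the bile acid uptake carrier of enterocytes, was at 145 ± 35.1 CPM against 534 ± 126 (n = 3 each), and fell 3.41-fold (log2 -1.77 ± 0.22, adjusted p = 6.37e-06). Slc51b, 1 subunit of the basolateral bile acid exporter, was at 405 ± 88.4 against 205 ± 38.7 CPM and rose 1.88-fold (0.91 ± 0.2, adjusted p = 0.00289). The other subunit, Slc51a, was at 0.53 ± 0.21 (adjusted p = 0.159), and the bile acid binding protein gene Fabp6 at 0.13 ± 0.22 (adjusted p = 0.846). Nr0b2 had at most 4 counts in any library and was not tested. The first-run tCDCA library had 265, 95.1 and 465 CPM of Fgf15, Slc10a2 and Slc51b, against 10.9, 183 and 286 in the removed DMSO replicate 1. For Slc10a2 the used second-run DMSO libraries were higher, at 405 to 658 CPM.

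**Figure D1:**
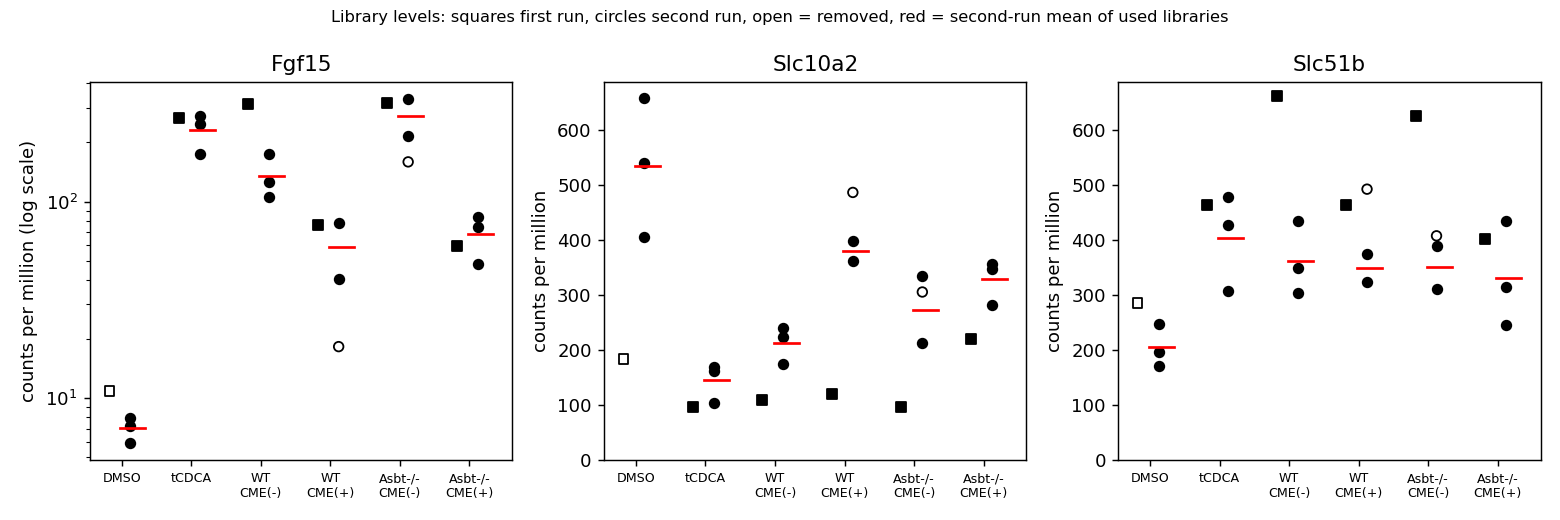
Levels of Fgf15 (log axis), Slc10a2 and Slc51b in each library, in CPM, by group. Squares are first-run and circles second-run libraries, open symbols are libraries the submitters removed, and red lines are means of the used second-run libraries, which for Fgf15 run from 7.03 with DMSO to 273 with Asbt-/- CME(-).

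Across the transcriptome 746 genes were called between tCDCA and DMSO, 331 higher and 415 lower, and 361 of them differed at least 2-fold. Lif, a cytokine gene, rose 5.06-fold (2.34 ± 0.33), Plaur, the urokinase receptor gene, 4.38-fold (2.13 ± 0.26), and Chac1, a glutathione-degrading enzyme gene of the ATF4 response, 3.51-fold (1.81 ± 0.25). Among the 10 largest increases were also Krt6a (5.11 ± 1.04), Sprr2h (3.79 ± 0.76), Vgf (2.2 ± 0.43), Ackr1 (1.93 ± 0.39), Il6 (1.88 ± 0.46) and Cxcl3 (1.87 ± 0.42). Krt6a was near the floor with DMSO, at 1.05 ± 0.98 CPM in the second run. In the single first-run libraries Vgf was at 3.72 CPM with tCDCA and 3.37 to 7.42 with the extracts. Sprr2h was at 147 CPM with tCDCA and 80.2 to 147 with the extracts there. Krt6a, Ackr1, Il6 and Cxcl3 were higher there with tCDCA than with each extract. Among the largest decreases were transporter genes: the amino acid carrier Slc43a2 (-2.28 ± 0.27), the phosphate carrier Slc34a2 (-2.33 ± 0.39), the fructose carrier Slc2a5 (-2.76 ± 0.6), the glucose carrier Slc2a2 (-2.74 ± 0.48) and Slc23a4 (-2.73 ± 0.66). Apol7a (-2.59 ± 0.34), Fam118a (-2.45 ± 0.35), the skeletal muscle actin gene Acta1 (-2.39 ± 0.31), Cyp4b1 (-2.3 ± 0.57) and Susd2 (-2.19 ± 0.55) completed them. Of 69 called genes named by the rule for this comparison, 22 passed the threshold in the same direction in all 19 alternatives, among them Fgf15, Slc10a2, Lif, Plaur, Chac1, Psat1, Slc7a11, Apol7a, Fam118a, Acta1, Slc34a2, Slc43a2, Vnn1, Dgat1, Dgat2, Npc1l1, Anpep, Slc5a1, Sult1b1, Irf7 and Mxi1. Slc51b was at 0.66 (adjusted p = 0.113) without tCDCA replicate 3 and DMSO replicate 3, and at 1.03 without the run term, and passed the threshold in neither.

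Genes of absorptive enterocytes fell together. Of 19 tested enterocyte markers 13 fell and none rose (17 fell adjusted over the list alone), with a median log2 change of -1.56. The brush border enzyme genes Anpep (-1.55 ± 0.22), Mgam (-1.2 ± 0.18) and Mep1a (-1.05 ± 0.19) and the glucose carrier gene Slc5a1 (-1.18 ± 0.2) were among them (camera adjusted p = 9.34e-25; adjusted p = 0.0248 with an estimated correlation). Of 14 genes of lipid absorption and lipoproteins 8 fell (13 adjusted over the list alone, median -1.36), among them the cholesterol uptake gene Npc1l1 (-1.7 ± 0.25), Slc27a4 (-1.5 ± 0.25) and the triglyceride synthesis genes Dgat1 (-1.17 ± 0.18) and Dgat2 (-0.91 ± 0.18). Camera gave 2.6e-17, and the adjusted p = 0.0397 with an estimated correlation. These lists share Apoa1, Apoa4, Fabp2 and Mttp. Of 13 bile acid receptors and carriers 4 fell (6 adjusted over the list alone, median -0.62), among them Slc10a2, Abcg2 (-0.69 ± 0.15) and Abcc2 (-0.89 ± 0.24), with camera at 0.000155 and adjusted p = 0.0124 with an estimated correlation. Of 16 PXR and CAR targets, genes of drug and bile acid metabolism, 4 fell (8 adjusted over the list alone, median -0.73): Sult1b1 (-1.04 ± 0.18), Ces2a (-1.5 ± 0.3), Cyp3a13 (-1.28 ± 0.25) and Cyp3a25 (-1.44 ± 0.32). Camera called that list at 3.02e-05, against adjusted p = 0.0558 with an estimated correlation.

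Of 17 genes of the ATF4 integrated stress response 11 rose (14 adjusted over the list alone, median 0.95), among them Chac1, the serine synthesis gene Psat1 (1.44 ± 0.23), the cystine carrier gene Slc7a11 (1.21 ± 0.24) and Cebpb (1.23 ± 0.27). Camera called it at 3.13e-13, with adjusted p = 0.0124 with an estimated correlation. Of 23 NF-kB and inflammatory genes 6 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.04); Il1b (1.01 ± 0.24), Cxcl1 (1.56 ± 0.36), Il6 and Nos2 (1.78 ± 0.48) were among them. Camera called it at 3.46e-07, against adjusted p = 0.0558 with an estimated correlation. Of 16 NRF2 targets 3 rose (3 adjusted over the list alone, median 0.22), Slc7a11, Me1 (1.07 ± 0.29) and Hmox1 (1.28 ± 0.35); camera gave 0.00318, and the adjusted p = 0.138 with an estimated correlation. Of 12 heat shock genes Hspa8 (0.64 ± 0.16) and Hsp90ab1 (0.57 ± 0.15) rose (3 adjusted over the list alone, median 0.28), with camera at 0.00319 and adjusted p = 0.221 with an estimated correlation. Of 11 antimicrobial genes of the epithelium 3 rose (4 adjusted over the list alone, median 0.68), Reg3g (0.86 ± 0.23), Ang4 (0.69 ± 0.2) and Nos2; camera gave 0.00318, and the adjusted p = 0.14 with an estimated correlation.

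Fry called 12 lists in this comparison. Among them were PXR and CAR targets (adjusted p = 0.0022) and NF-kB and inflammatory genes (0.0042), which camera lost with an estimated correlation. Enteroendocrine markers (0.0476, higher) and T and NK cell markers (0.0364, lower) were called by fry and not by camera.

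Of 20 interferon-stimulated genes Irf7 (-1.39 ± 0.24) and Oasl2 (-0.93 ± 0.27) fell (2 adjusted over the list alone, median -0.54), with camera at 0.00555 and adjusted p = 0.394 with an estimated correlation. No gene of 7 for MHC class II and antigen presentation was called (4 lower adjusted over the list alone, median -1.11; camera 0.00025, adjusted p = 0.268 with an estimated correlation).

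Of 8 Paneth cell markers, genes of the antimicrobial cells of the crypt, Ang4, Defa30 (0.73 ± 0.2) and Mmp7 (0.63 ± 0.19) rose (8 adjusted over the list alone, median 0.7), with camera at 1.27e-06 and adjusted p = 0.18 with an estimated correlation. No fibroblast marker of 12 was called (1 higher and 4 lower adjusted over the list alone, median -0.45; camera 0.013, adjusted p = 0.335 with an estimated correlation). Camera did not call the 16 enteroendocrine markers (median 0.18, adjusted p = 0.0809), of which Tac1 (1.42 ± 0.25), Gcg (0.93 ± 0.22) and Cck (0.95 ± 0.23) rose. Nor did it call the 11 goblet cell markers (-0.04, 0.948), of which Ccl6 (0.56 ± 0.16) rose while Fcgbp (-0.71 ± 0.17) and Zg16 (-0.56 ± 0.17) fell. Medians and camera adjusted p of further cell type lists were 0.34 and 0.403 for tuft cells, -0.85 and 0.0808 for T and NK cells, -0.51 and 0.399 for B and plasma cells, and -0.13 and 0.969 for myeloid cells (1 of 14 rose). They were -0.03 and 0.438 for smooth muscle, 0.16 and 0.969 for endothelium, 0.03 and 0.889 for enteric neurons and glia, and -0.66 and 0.963 for adipocytes and mesothelium. For erythrocytes and pancreas (2 of 5 fell) they were -0.18 and 0.134, and for 10 Wnt and crypt stem cell markers (1 rose) 0.03 and 0.709. Mitochondrial rRNA held 5.29% of counts in tCDCA replicate 3, against 28.14 and 33.14% in the other second-run tCDCA libraries and 19.46 to 34.6% with DMSO. The mitochondrially encoded mRNAs had a median of -0.02 (camera adjusted p = 0.423).

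The FXR target list itself, in which Fgf15, Slc51b and Sqstm1 (0.75 ± 0.15) rose and Slc10a2 and Abcc2 fell among 9 tested members (5 higher and 2 lower adjusted over the list alone, median 0.53), was not called by camera (adjusted p = 0.0825). Camera asks for a shift in 1 direction, and members called both ways weaken it, so this does not show that the targets were unchanged. Of 22 PPAR targets and fatty acid oxidation genes 3 fell, among them Vnn1 (-2.07 ± 0.37) and Creb3l3 (-1.67 ± 0.43) (2 higher and 4 lower adjusted over the list alone, camera 0.0977). Of 13 LXR targets and lipogenesis genes Fasn rose (0.77 ± 0.22) while Abcg5 (-0.88 ± 0.23) and Lpcat3 (-0.74 ± 0.2) fell (1 and 3 adjusted over the list alone, camera 0.423). Of 18 hypoxia and glycolysis genes Ndrg1 (0.74 ± 0.17) and Car9 (0.53 ± 0.15) rose and Mxi1 (-1.06 ± 0.22) fell (5 and 1 adjusted over the list alone, camera 0.0595). Medians and camera adjusted p were 0.3 and 0.0599 for proliferation, 0.09 and 0.334 for the unfolded protein response, 0.06 and 0.889 for immediate early genes (1 rose and 1 fell), 0.08 and 0.957 for p53 targets (1 fell), and 0.02 and 0.889 for cholesterol synthesis (1 of 25 fell). They were -0.04 and 0.438 for VDR targets, 0.03 and 0.913 for AhR targets, and -0.04 and 0.948 for retinoic acid targets. Over all comparisons the median, mean and camera direction of a list differed in sign in 87 of 456 list results, none of them called by camera. With tCDCA these were the AhR, retinoic acid, cholesterol synthesis, myeloid, neuron and glia, and adipocyte and mesothelial lists, the last with a median of -0.66, a mean of -0.24 and the direction up.

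The count of 746 rested on some of the libraries and terms: it was 327 without DMSO replicate 3, 496 without tCDCA replicate 4, 324 without tCDCA replicate 3 and DMSO replicate 3 (281 shared with the 746), and 464 with DMSO replicate 1 added, as well as 418 with all 24 libraries and 298 with the compared groups alone. With no scaling factors it was 427 (229 higher, 198 lower, so that more genes rose than fell), and with no run term 176 (50 and 126). In the first run, tCDCA replicate 1 against the removed DMSO replicate 1 had the same direction in 76.1% of 744 of these genes, with a median change of 0.24 in that direction, against 0.98 in the comparison itself.

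**Figure D2:**
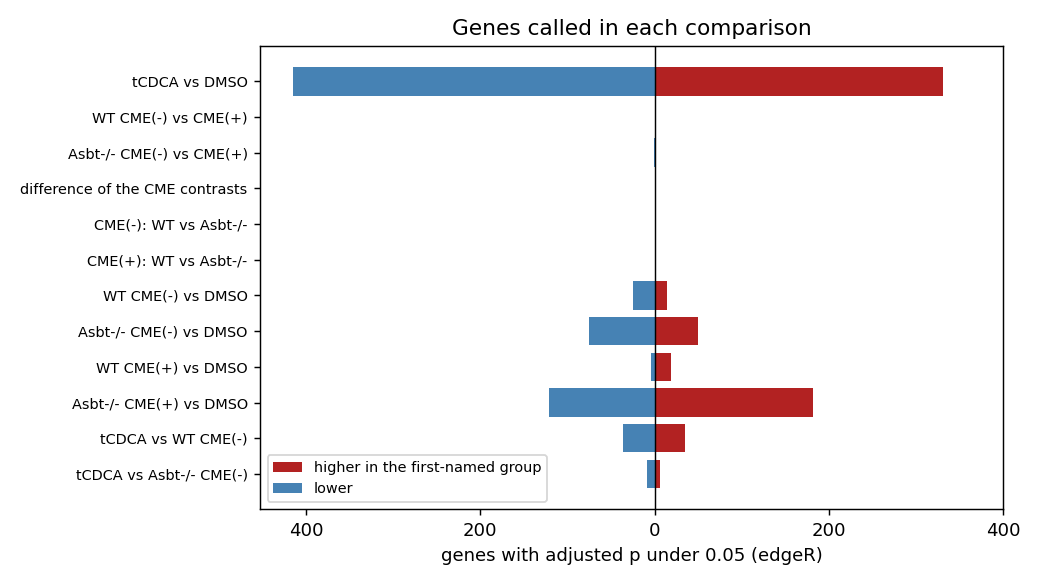
Number of genes with an adjusted p under 0.05 (edgeR) in each of the 12 comparisons, higher in the first-named group to the right and lower to the left, on 1 linear axis starting at 0. tCDCA against DMSO had 331 higher and 415 lower genes, and no comparison between the extracts had more than 3.

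Extracts of WT donors with and without bile acids were compared to ask which genes respond to the bile acids of the extract. Fgf15 was at 135 ± 35.7 CPM (SD, n = 3) with CME(-) and 59.1 ± 26.5 (n = 2) with CME(+) in the second run, and at 312 and 75.9 CPM in the single first-run libraries. The difference of 1.46 ± 0.3 log2 units (interval 0.84 to 2.08, 2.75-fold) was not past the threshold in edgeR (adjusted p = 0.255). It was past it with DESeq2 and with no count filter (adjusted p = 7.93e-11). Slc10a2 was at -0.64 ± 0.22 (adjusted p = 0.538), Slc51b at 0.19 ± 0.19 (0.934), Fabp6 at 0.27 ± 0.22 (0.899) and Slc51a at -0.01 ± 0.21 (0.998). The other genes with the smallest p, all at an adjusted p of 0.255, were Cdx2, a transcription factor gene of intestinal identity (-1.26 ± 0.27), Cdc42ep2 (-0.96 ± 0.21), Gna11 (-0.72 ± 0.16) and Aldh2 (-0.9 ± 0.21).

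No gene was called in this comparison by edgeR (831 at an unadjusted p under 0.05), 4 were called by DESeq2 (1 higher, 3 lower), and 22 (16 higher, 6 lower) with the extract donor as a block in the paired groups alone. The same groups alone with the run term in place of the block gave 0. With that block Gna11 (-0.74) and Aldh2 (-0.86) fell and Fgf15 was at 1.41, not past the threshold. Camera called 8 lists, none of which had a called member or held with an estimated correlation. Mitochondrially encoded mRNAs had a median of 0.48 (5 of 11 higher adjusted over the list alone; camera 1.1e-08, adjusted p = 0.0834 with an estimated correlation). Beside this, the mitochondrial rRNA share was 26.22 to 31.86% with CME(-) and 19.51 to 22.03% with CME(+) in the second run. Heat shock genes had a median of 0.3 (camera 2.34e-05, adjusted p = 0.179 with an estimated correlation), smooth muscle markers 0.44 (2.34e-05, adjusted p = 0.481 with an estimated correlation) and immediate early genes 0.25 (0.0149, adjusted p = 0.481 with an estimated correlation). Medians were negative for antimicrobial genes (-0.31; camera 0.0383, adjusted p = 0.481 with an estimated correlation) and LXR targets (-0.16; 0.0387, adjusted p = 0.179 with an estimated correlation). They were negative too for cholesterol synthesis (-0.18; 0.0383) and enterocyte markers (-0.15; 0.037), both at an adjusted p = 0.856 with an estimated correlation. In none of these 7 lists was a gene called over the list alone. With the donor block camera called 8 lists, in which the FXR targets (adjusted p = 0.0462) stood in place of the enterocyte markers, and none held with an estimated correlation.

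The same contrast with extracts of Asbt-/- donors called 3 genes. Fgf15 was at 273 ± 80.5 CPM (SD, n = 2) with CME(-) and 68.6 ± 18.2 (n = 3) with CME(+) in the second run and at 318 and 59 CPM in the first. It rose by 2.07 ± 0.28 log2 units, 4.2-fold (adjusted p = 0.00567). Defa5 (ENSMUSG00000074439), a defensin gene of Paneth cells with near-identical copies, was at 197 ± 60.1 against 89.7 ± 6.35 CPM and rose 2.58-fold (1.37 ± 0.22, adjusted p = 0.00567). Car4 (ENSMUSG00000000805), a membrane-bound carbonic anhydrase gene, was at 57.5 ± 4.1 against 147 ± 31.9 CPM and fell 2.17-fold (-1.12 ± 0.21, adjusted p = 0.0325). Slc10a2 was at -0.53 ± 0.22 (adjusted p = 0.605), Slc51b at 0.25 ± 0.19 (0.854), Fabp6 at 0.4 ± 0.22 (0.736) and Slc51a at 0.07 ± 0.21 (0.975).

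Camera called 10 lists in this comparison, 3 of which held with an estimated correlation, each at an adjusted p of 0.0461. These were the heat shock genes (6 of 12 higher adjusted over the list alone, median 0.45, camera 9.56e-09), the mitochondrially encoded mRNAs (6 of 11 higher adjusted over the list alone, median 0.46, camera 1.36e-08) and the B and plasma cell markers (none of 6 over the list alone, median -0.16, camera 3.52e-06). Beside them, the mitochondrial rRNA share was 24.6 to 27.41% with CME(-) and 17.57 to 19.02% with CME(+) in the second run. Paneth cell markers had a median of 0.76 (7 of 8 higher adjusted over the list alone; camera 4.17e-12, adjusted p = 0.0651 with an estimated correlation). Smooth muscle markers had one of 0.72 (7 of 11 higher adjusted over the list alone; 1.36e-08, adjusted p = 0.107 with an estimated correlation). Of the FXR targets Fgf15 rose (1 of 9 adjusted over the list alone, median 0.27; 0.00208, adjusted p = 0.0688 with an estimated correlation). Antimicrobial genes had a median of -0.52 (1 higher and 4 lower of 11 adjusted over the list alone; 0.000332, adjusted p = 0.0688 with an estimated correlation). LXR targets had one of -0.1 (none over the list alone; 0.0257, adjusted p = 0.0688 with an estimated correlation). Immediate early genes had a median of 0.27 (3 of 14 higher adjusted over the list alone; 0.0135, adjusted p = 0.284 with an estimated correlation). NF-kB and inflammatory genes had one of 0.21 (1 of 23; 0.0383, adjusted p = 0.521 with an estimated correlation). Fry called 7 lists: the 3 that held, FXR targets, LXR targets and Paneth cell markers (adjusted p = 0.0375 each) and antimicrobial genes (0.0486). With the extract donor as a block it called 0.

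With the extract donor as a block in the paired groups alone, 19 genes were called (9 higher, 10 lower), among them the 3. Fgf15 was then at 2.19 (adjusted p = 0.0047), and none of the 10 lists that camera called held with an estimated correlation (adjusted p = 0.613 for each). The same groups alone with the run term in place of the block gave 75 calls, so the rise from 3 to 19 cannot be put down to the pairing. With the replicate number as a block over all groups 1 of the 3 was called, Defa5, while Fgf15 (2.05) and Car4 (-1.09) were not past the threshold. None of the 3 genes passed in all 19 alternatives. Calls were lost for Fgf15 (1.85) and Car4 (-0.99) without Asbt-/- CME(-) replicate 2, for Defa5 (adjusted p = 0.132) and Car4 (-1.05) without CME(-) replicate 4, and for Car4 (-1.13, -1.12 and -1.01) without CME(+) replicate 1, 2 or 3. With all 24 libraries none of the 3 was called, and Fgf15 was at 1.91. The count was 10 without CME(-) replicate 1, 1 without CME(-) replicate 2 or 4, 54 with DESeq2 (26 higher, 28 lower) and 0 with no scaling factors.

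Whether the response to CME(-) over CME(+) differed between donors was tested as an interaction. For Fgf15 the difference was -0.61 ± 0.4 (interval -1.45 to 0.24, adjusted p = 1), and no gene was called by edgeR (491 at an unadjusted p under 0.05) or by DESeq2 (0). The genes with the smallest p were Slc22a18 (-1.43 ± 0.38), Gucy1b1 (-1.59 ± 0.45), Defa5 (-1.05 ± 0.31), Tgfbi (-0.94 ± 0.29) and Mptx2 (-0.93 ± 0.28), all at an adjusted p of 1. The other FXR genes lay between -0.13 and -0.06. Camera called 2 lists. Paneth cell markers had a median difference of -0.66 (1 of 8 lower adjusted over the list alone; camera 3.5e-07, adjusted p = 0.535 with an estimated correlation). B and plasma cell markers had one of 0.34 (none of 6; 0.0071, adjusted p = 0.535 with an estimated correlation).

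Extracts of both donors were also compared directly, to ask whether loss of the carrier in the donor changes what the extract does. With CME(-), Fgf15 was at -0.7 ± 0.28 for WT against Asbt-/- (interval -1.28 to -0.11, adjusted p = 0.997), and with CME(+) at -0.09 ± 0.29 (interval -0.7 to 0.52, adjusted p = 1). With CME(-), Slc10a2 was at -0.2 ± 0.22 (interval -0.65 to 0.24) and Slc51b at 0.03 ± 0.19 (-0.36 to 0.42). No gene was called by edgeR with CME(-) (531 at an unadjusted p under 0.05) or CME(+) (556), and DESeq2 called 0 in each. The smallest p belonged with CME(-) to Erich4 (1.18 ± 0.28, adjusted p = 0.791), Eapp (0.8 ± 0.21), Agap3 (-1.29 ± 0.34), Lmbr1l (1.21 ± 0.33) and Klhl7 (1.04 ± 0.29), the last 4 at 0.997. With CME(+) it belonged to Prpf4 (-1.13 ± 0.26), Tat (-1.01 ± 0.28), Mef2c (-1.34 ± 0.38), Synpo (0.73 ± 0.21) and Alkbh8 (-1.2 ± 0.35), all at 1.

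Camera called 6 lists with CME(-), each at an adjusted p = 0.91 with an estimated correlation: lipid absorption (median 0.35, camera 0.000758), interferon-stimulated genes (0.42, 0.00267), enterocyte markers (0.28, 0.0036), mitochondrially encoded mRNAs (0.24, 0.0356), Paneth cell markers (-0.28, 0.0036) and heat shock genes (-0.15, 0.0354). It called 5 with CME(+), each at an adjusted p = 0.581 with an estimated correlation: lipid absorption (0.5, 9.55e-07), enterocyte markers (0.29, 2.3e-05), Paneth cell markers (0.28, 0.000115), mitochondrially encoded mRNAs (0.31, 0.00843) and B and plasma cell markers (-0.75, 0.00384). None of their genes was called, and adjusted over the list alone 1 Paneth cell marker was higher with CME(+) of WT donors. Fry called 0 lists in both comparisons, as in the interaction and between the WT extracts.

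Against DMSO, Fgf15 rose with every extract: by 4.51 ± 0.38 with WT CME(-) (22.8-fold, adjusted p = 5.62e-06), 5.21 ± 0.39 with Asbt-/- CME(-) (37-fold, 8.99e-07), 3.05 ± 0.38 with WT CME(+) (8.28-fold, 0.00138) and 3.14 ± 0.36 with Asbt-/- CME(+) (8.82-fold, 0.000136). Slc10a2 fell with WT CME(-) (-1.32 ± 0.22, adjusted p = 0.0036) and Asbt-/- CME(-) (-1.12 ± 0.24, 0.0205), and was at -0.68 ± 0.23 (0.295) and -0.59 ± 0.22 (0.166) with the CME(+) extracts. In the first run it was at 109, 96.7, 119 and 219 CPM with the extracts in this order, against 183 in the removed DMSO replicate 1. Slc51b rose with WT CME(-) (0.92 ± 0.2, adjusted p = 0.0274) and Asbt-/- CME(-) (0.88 ± 0.21, 0.03), and was at 0.73 ± 0.21 (0.168) and 0.64 ± 0.2 (0.0739) with the CME(+) extracts. With no count filter these 4 values with CME(+) were past the threshold (adjusted p = 0.00924 to 0.0472). The intestinal carrier genes Slc13a2, for citrate, and Slc6a19, for neutral amino acids, fell with WT CME(-) (-1.72 ± 0.22 and -1.09 ± 0.2) and Asbt-/- CME(-) (-1.73 ± 0.24 and -1.71 ± 0.22), and Slc13a2 also with WT CME(+) (-1.26 ± 0.23). With Asbt-/- CME(+), looked up after the values were seen, both fell too (-1.43 and -1.03). Plaur rose with both CME(-) extracts (1.39 ± 0.27 and 1.22 ± 0.28), but a higher level was not particular to them. In the second run it was at 25.5 and 23 CPM with WT and Asbt-/- CME(-). It was at 19.8 and 25.7 CPM with WT and Asbt-/- CME(+), against 10.7 CPM with DMSO. Lrg1 rose with both CME(+) extracts (1.69 ± 0.28 and 2 ± 0.27). Of the named called genes, Fgf15 in each comparison, Erich4 with Asbt-/- CME(-) (-1.9 ± 0.29) and Lrg1 with Asbt-/- CME(+) passed in every alternative.

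WT CME(-) called 39 genes against DMSO (14 higher, 25 lower), Asbt-/- CME(-) 125 (50 and 75), WT CME(+) 23 (19 and 4) and Asbt-/- CME(+) 303 (182 and 121). Lipid absorption genes had medians of -0.69, -1, -0.43 and -0.94 in this order, with 1, 1, 0 and 3 of 14 called lower (4, 11, 0 and 9 adjusted over the list alone); Dgat1 fell in all but WT CME(+). Camera gave 5.41e-09, 3.3e-14, 0.000165 and 5.13e-12, against adjusted p = 0.18, 0.126, 0.346 and 0.118 with an estimated correlation. Enterocyte markers had medians of -0.62, -0.86, -0.42 and -0.87, with 1 of 19 called, Treh with Asbt-/- CME(+) (-1.23 ± 0.31), and 5, 17, 0 and 10 lower adjusted over the list alone. Camera gave 3.17e-11, 3.6e-15, 0.000165 and 1.1e-11, against adjusted p = 0.18, 0.126, 0.349 and 0.136 with an estimated correlation. ATF4 genes had medians of 0.42, 0.5, 0.33 and 0.43, and Chac1 and Slc7a5 rose with WT CME(+) (1.16 ± 0.26 and 1.38 ± 0.29) and Asbt-/- CME(+) (1.29 ± 0.25 and 1.14 ± 0.27). Adjusted over the list alone 4, 9, 4 and 7 of 17 were higher (0, 1, 0 and 1 lower), camera gave 3.04e-05, 2.41e-05, 2.4e-05 and 1.55e-05, and with an estimated correlation the adjusted p = 0.18, 0.152, 0.297 and 0.126. Interferon-stimulated genes had medians of -0.36, -0.74, -0.51 and -0.57, and Oasl2 and Irf7 fell with both Asbt-/- extracts (-1.47 ± 0.3 and -1.21 ± 0.26 with CME(-), -1.31 ± 0.27 and -0.81 ± 0.23 with CME(+)). Adjusted over the list alone 1, 2, 1 and 4 of 20 were lower, camera gave 0.00667, 9.33e-07, 0.00226 and 4.53e-05, and with an estimated correlation the adjusted p = 0.461, 0.167, 0.349 and 0.278.

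Camera called the mitochondrially encoded mRNAs, with negative medians against DMSO, in both CME(+) groups, and neither result held with an estimated correlation. For Asbt-/- the median was -0.93 (5 of 11 fell, 6 adjusted over the list alone, mt-Co2 -0.96 ± 0.17, mt-Cytb -0.96 ± 0.18, camera 3.7e-09, adjusted p = 0.0808 with an estimated correlation). For WT the median was -0.5 (0 called, 5 lower adjusted over the list alone; 8.43e-06, adjusted p = 0.297 with an estimated correlation). Mitochondrial rRNA made up 17.57 to 22.03% of counts in these second-run libraries and 19.46 to 34.6% with DMSO. Smooth muscle markers had medians of -0.55 and -0.47 there (camera 0.000221 and 0.000208, adjusted p = 0.278 and 0.346 with an estimated correlation), and Hhip fell with Asbt-/- CME(+) (-1.41 ± 0.33). Heat shock genes had a median of 0.55 with Asbt-/- CME(-), where Hspa8 (0.71 ± 0.17) and Hsp90ab1 (0.65 ± 0.17) rose (8 of 12 adjusted over the list alone; camera 6.07e-09, adjusted p = 0.0637 with an estimated correlation). With WT CME(-) their median was 0.41 (4 adjusted over the list alone; 3.67e-06, adjusted p = 0.18 with an estimated correlation). Paneth cell markers had a median of 0.71 with Asbt-/- CME(-), where Defa30 rose (0.88 ± 0.21; 6 of 8 adjusted over the list alone; camera 1e-07, adjusted p = 0.167 with an estimated correlation). In total camera called 12, 10, 14 and 13 lists against DMSO, and none held with an estimated correlation. Fry called 0, 5, 0 and 7. Lipid absorption (adjusted p = 0.0344 and 0.0162), enterocyte markers (0.044 and 0.0338) and ATF4 genes (0.0487 and 0.0162) were among them with both Asbt-/- extracts.

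These counts rested on single libraries and settings. They were 117, 272, 95 and 498 with DESeq2 and 107, 258, 83 and 476 with no count filter. Without DMSO replicate 3 they were 7, 19, 5 and 56, without DMSO replicate 4 they were 8, 61, 12 and 190, and with no run term 2, 3, 3 and 3. WT CME(-) called 69 without DMSO replicate 2, and 14, 15 and 8 without its own replicate 1, 2 or 3. Asbt-/- CME(-) called 50 and 10 without its replicate 1 or 4, WT CME(+) 9, 6 and 13 without its replicate 1, 3 or 4, and Asbt-/- CME(+) called 126, 149 and 135 without its replicate 2, 3 or 4. With no scaling factors the higher and lower counts were 1 and 9 for WT CME(-), 5 and 13 for Asbt-/- CME(-), and 269 and 18 for Asbt-/- CME(+).

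Genes called between tCDCA and DMSO moved in the same direction in the extracts in 98.1% (WT CME(-)), 98.5% (Asbt-/- CME(-)), 95.4% (WT CME(+)) and 95.7% (Asbt-/- CME(+)) of cases, with medians of 0.52, 0.63, 0.45 and 0.58 in that direction. In simulations all libraries were drawn around fitted levels, with the extract groups unchanged and the simulated DMSO libraries shared between the contrasts. They gave 71.8, 70.7, 70.8 and 71.8%, and medians of 0.18, 0.18, 0.18 and 0.17. On average 1348 genes were called with tCDCA in these simulations, against 746 in the data. Correlations of fold changes across genes, which are not independent replicates, were 0.66, 0.66, 0.62 and 0.69 against 0.35, 0.33, 0.34 and 0.36 simulated. Covariances were 0.269, 0.311, 0.281 and 0.307 against 0.139, 0.14, 0.141 and 0.139. Genes called in both, whatever their direction, numbered 37, 101, 17 and 170, and in the simulation 0, 0.1, 0.1 and 0. Independent lists would share 1.1, 3.6, 0.6 and 8.4 in the same direction. That value leaves out opposite directions, so it is too low a baseline for these counts. A simulation added later, with smaller tCDCA effects, called 738 genes. Averaged over the extracts it gave 68.9% in the same direction, a median of 0.15, a correlation of 0.41 and a covariance of 0.137. With the 3 DMSO libraries divided between the contrasts, 1 against 2 in all 6 ways, 65 to 96.3% of the genes called with tCDCA moved in the same direction, with medians of 0.19 to 0.73 (14995 genes passed the filter). On the 13125 genes of the other comparisons, covariances were then 0.079 to 0.189. They lay below the undivided 0.269 to 0.311, so part of the shared direction may come from the shared controls. In the first run these shares were lower: against the removed DMSO replicate 1, 40.2% of 744 genes in WT CME(-), 62.5% in Asbt-/- CME(-), 46.5% in WT CME(+) and 31.7% in Asbt-/- CME(+) replicate 1 had the direction of tCDCA.

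tCDCA, a single bile acid, and the CME(-) extracts are given at 200 µM in the second run. Fgf15 with tCDCA was at 0.47 ± 0.26 relative to WT CME(-) (interval -0.08 to 1.02, adjusted p = 0.551) and -0.23 ± 0.28 relative to Asbt-/- CME(-) (-0.81 to 0.36, 0.909). Slc10a2 was at -0.46 ± 0.2 (interval -0.87 to -0.04, adjusted p = 0.402) and -0.66 ± 0.22 (-1.1 to -0.21, 0.313), and Slc51b at -0.01 ± 0.18 (-0.37 to 0.35) and 0.02 ± 0.19 (-0.37 to 0.41). Relative to WT CME(-) tCDCA called 71 genes (35 higher, 36 lower), and relative to Asbt-/- CME(-) 15 (6 and 9). Lif rose in both (1.55 ± 0.28 and 1.62 ± 0.32). Acta1 (-2.09 ± 0.3 and -1.83 ± 0.31), the clock gene Dbp (-1.69 ± 0.27 and -1.77 ± 0.29), Slc2a9 (-1.39 ± 0.29 and -1.45 ± 0.31) and Prlr (-1.24 ± 0.21 and -1.19 ± 0.22) fell in both. Relative to WT CME(-) the chemokine genes Ccl7 (2.09 ± 0.3), Ccl4 (1.99 ± 0.43) and Ccl2 (1.21 ± 0.26), the collagenase gene Mmp13 (1.53 ± 0.29) and Ptges (1.46 ± 0.29) rose. Vnn1 (-1.61 ± 0.34), Anpep (-1.24 ± 0.2) and Abcc2 (-1.21 ± 0.23) fell.

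Camera called 12 lists relative to WT CME(-) and 14 relative to Asbt-/- CME(-), and none held with an estimated correlation. Fry called 5 and 3, with NF-kB (adjusted p = 0.00903 and 0.0462) and ATF4 genes (0.00903 and 0.0462) in both. NF-kB and inflammatory genes had medians of 0.52 and 0.7 (2 of 23 and 0 called; 9 and 6 higher adjusted over the list alone; camera 4.05e-08 and 4.09e-07, adjusted p = 0.0598 and 0.126 with an estimated correlation). ATF4 genes had medians of 0.53 and 0.42 (2 and 0 of 17 called, 10 and 5 higher adjusted over the list alone; camera 7.19e-09 and 4.14e-07, adjusted p = 0.0598 and 0.126 with an estimated correlation). Enterocyte markers had medians of -0.86 and -0.47 (2 and 0 of 19 called, 10 and 5 lower adjusted over the list alone; camera 1.58e-15 and 1.81e-07, adjusted p = 0.0988 and 0.25 with an estimated correlation).

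The 71 became 135 without tCDCA replicate 1, 36 without replicate 3, 30 without replicate 4, and 36, 42 and 32 without WT CME(-) replicate 1, 3 or 4, and with no scaling factors the directions were 40 and 10. The 15 became 54, 6, 4 and 4 without tCDCA replicate 1, 2, 3 or 4, 58, 0 and 2 without Asbt-/- CME(-) replicate 1, 2 or 4, and 68 (38 higher, 30 lower) with DESeq2. In comparisons added later, tCDCA called 203 genes relative to WT CME(+) (64 higher, 139 lower; Fgf15 1.93 ± 0.3, adjusted p = 0.00209). It called 253 relative to Asbt-/- CME(+) (114 and 139; Fgf15 1.84 ± 0.27, adjusted p = 0.00111).

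The comparisons of tCDCA with DMSO and of CME(-) with CME(+) share no library. Across genes the Pearson correlations of their fold changes were -0.032 for WT and 0.011 for Asbt-/- (0.011 and -0.072 in the second run alone). The extract contrasts of both donors correlated only weakly with each other too (Pearson 0.096, Spearman 0.151), so these values do not show that the responses differed. Fgf15 (1.46 and 2.07) and Slc10a2 (-0.64 and -0.53) had the direction of tCDCA in both. Fgf15 was the 1 gene that rose both with tCDCA and with Asbt-/- CME(-) over CME(+), where 0.0504 shared genes were expected (Fisher's exact test, p = 0.0498).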

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

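Of the tests in this part, the simulation of the shared DMSO libraries, the comparison of proximal and distal ileal markers and the splits of the libraries (except those of tCDCA and DMSO) were chosen before their results were seen, the division of the DMSO libraries after the pattern was known but before its own result was seen, and the other tests after.

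Genes called between tCDCA and DMSO moved the same way in all 4 extract groups, with a median of at least 0.45 log2 units in the direction of tCDCA. A lower share of enterocytes alone would raise the markers of every other cell type alike. Over 8 lists of other cell types the median ran from -0.85 (T and NK cells) to 0.7 (Paneth cells), which is no such even rise. But no member of the T and NK list was called, and camera did not call the list (adjusted p = 0.0808). Several cell types may also have changed together, so a change in tissue composition stays open. Simulated unchanged groups with shared DMSO libraries reached a median of up to 0.2, under 0.45 as the bound set in advance asked. But genes were drawn independently there, and 1348 were called with tCDCA on average, against 746 in the data. Simulations added later, with smaller effects, reached 0.18 where 738 genes were called. At 3 times the dispersion, where 90 genes were called, they reached 0.51, over the bound. With the DMSO libraries divided between the contrasts, all 24 medians (0.19 to 0.73) lay above the 0.05 set for no change, though the lowest not above the bound of 0.2. Covariances were then 0.079 to 0.189 against 0.269 to 0.311 undivided, so part of the pattern may come from the shared libraries. Fragments from a more proximal position in the DMSO group stay open too, since the proximal markers had a median of -0.64, but the distal markers were as low (-0.63), so the bound set in advance, met by 0.01, was a poor one. Second-run DMSO libraries that stand apart from the extracts remain possible, because in the first run a mean of 45.2% of the genes (31.7 to 62.5%) had the direction of tCDCA in the extracts and 76.1% in tCDCA itself, against a single DMSO library at another DMSO concentration.

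Fgf15 stayed above DMSO in the CME(+) groups, by 3.05 ± 0.38 and 3.14 ± 0.36 log2 units. DMSO libraries that stand apart could account for part of it, but in the first run too the lower of the CME(+) libraries had 5.42 times the Fgf15 level of the removed DMSO replicate 1 (59.1 against 10.9 CPM), a comparison of single libraries. An FXR agonist left in the CME(+) extracts or formed from them may also act: Slc10a2 and Slc51b, its other responses, were not past the threshold there (smallest adjusted p = 0.0739), but with no count filter all 4 values were, in the direction of an agonist (adjusted p = 0.00924 to 0.0472). That setting called more genes in general, 83 against 23 with WT CME(+) and 476 against 303 with Asbt-/- CME(+). In other alternatives the adjusted p reached 0.827 and 0.558 for Slc10a2 and 0.684 and 0.384 for Slc51b. The bile acid content of the extracts is not in the labels, and these explanations cannot be told apart here.

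Mitochondrially encoded mRNAs had medians of 0.48 for WT and 0.46 for Asbt-/- donors with CME(-) over CME(+), with no member called in either contrast. Camera called the list in both, with adjusted p = 0.0834 and 0.0461 with an estimated correlation, and 0.622 and 0.613 with the extract donor as a block. Mitochondrial rRNA had a larger share of the counts in the CME(-) libraries and may be tied to it: with the rRNA left out the lower median was 0.46, but that setting moved next to nothing and so decides nothing. A difference in 1 run cannot be told apart either, since both medians were 0.29 in the first run, with 1 library per group, against 0.55 and 0.59 in the second. No biological explanation was tested.

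Camera on the interaction called the Paneth cell markers and the B and plasma cell markers, with median differences of -0.66 and 0.34 for WT less Asbt-/- donors. Neither held with an estimated correlation (adjusted p = 0.535 for both), fry called 0 lists, and no gene was called, so a difference between donors is not shown. Asbt-/- CME(+) replicate 1 lay far from the rest of its group in its share of mitochondrial rRNA, 6.78% against 17.57 to 19.02%. It is the group's 1 first-run library, and among 30 groups and measures tested, 1.5 would stand out by chance. Fgf15 was above the used second-run DMSO libraries (5.95 to 7.95 CPM) in 2 libraries that the submitters removed: 159 CPM (interval 141 to 179) in Asbt-/- CME(-) replicate 3 and 18.3 CPM (13.4 to 24.4) in WT CME(+) replicate 2.

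Other splits of the same libraries into groups of the same sizes tested the counts of called genes. For tCDCA against DMSO 1 of 35 splits, the real one, gave as many, with 746 genes against at most 405 in another. The same held for WT CME(-) against DMSO (1 of 35, 39 against 31), Asbt-/- CME(+) against DMSO (1 of 35, 303 against 232) and tCDCA against WT CME(-) (1 of 35, 71 against 1). That share is under 0.05 for these 4, but some of the splits change how the first-run libraries are divided between the groups. Among the 20 that leave the first-run libraries divided as they were, the real one again stood alone in each, with the same highest other counts, and 20 are too few for a share under 0.05. The 405 and 232 come from the real grouping with replicate 1 of tCDCA or Asbt-/- CME(+) moved across, and so hold much of the real contrast. They count among the 20 because replicate 1 then makes up the group of 4 with the DMSO libraries. The 31 come from the real grouping with WT CME(-) replicate 4 and DMSO replicate 2 exchanged. A mixed grouping within the second run thus came near the real 39. Chance cannot be excluded for the Asbt-/- CME(-) and CME(+) contrast (2 of 35, 3 against 4), where the 4 come from the real grouping with the first-run libraries exchanged, which again holds much of the real contrast. Nor can it be excluded for tCDCA against Asbt-/- CME(-) (2 of 35, 15 against 60). The 60 point to a structure of the samples: that split is the real grouping with tCDCA replicate 1 moved across, and the real contrast called 54 genes without this library and 80 in the second run alone. Among the 20 splits that keep the runs it was 1 of 20, 15 against 1, again too few. For Asbt-/- CME(-) and WT CME(+) against DMSO the 10 splits are too few (1 of 10 each, 125 against 4 and 23 against 0). With 0 genes called in edgeR, every split gave as many for WT CME(-) against CME(+) (35 of 35, highest other 1), for the CME(-) extracts of both donors (35 of 35, 2), for the CME(+) extracts (35 of 35, 2) and for the interaction (100 of 100, 3).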

How the results depend on the processing

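The tests with the rRNA left out, with DMSO replicate 1 added, and with tCDCA replicate 3 and DMSO replicate 3 both left out were chosen after the data had been examined. Over the alternatives 3808 of the values for named genes kept direction and side of the threshold, 1309 lost the threshold, 24 gained it and 74 changed sign. Fgf15 kept its call and direction in every alternative against DMSO: 4.77 to 5.15 log2 units with tCDCA (adjusted p up to 0.000241), 4.26 to 4.69 with WT CME(-), 4.98 to 5.34 with Asbt-/- CME(-), 2.72 to 3.27 with WT CME(+) (up to 0.0329) and 2.96 to 3.38 with Asbt-/- CME(+) (up to 0.00581). Between the extracts it ran from 1.11 to 1.73 for WT and from 1.85 to 2.24 for Asbt-/- donors (up to 0.0903). Slc10a2 with WT CME(-) against DMSO ran from -1.52 to -1.14 (adjusted p up to 0.551) and with Asbt-/- CME(-) from -1.43 to -0.92 (up to 0.405), and Slc51b from 0.8 to 1.09 (up to 0.466) and 0.77 to 1.11 (up to 0.213). With WT CME(+) and Asbt-/- CME(+) against DMSO, Slc10a2 ran from -0.87 to -0.41 (adjusted p from 0.0472 to 0.827) and from -0.83 to -0.36 (0.0347 to 0.558). Slc51b ran from 0.62 to 0.92 (0.0205 to 0.684) and from 0.43 to 0.88 (0.00924 to 0.384). Self-tests recovered 38.5% of genes changed 2-fold between tCDCA and DMSO and 20.9% between the WT extracts, so a missing call does not show that a gene was unchanged. Where a value moved, the cause was not tested.

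With no scaling factors, which shifts the median of all genes by up to 0.222 log2 units, calls were 427 for tCDCA against DMSO (229 higher, 198 lower; 746 as 331 and 415 in the main analysis), 10 for WT CME(-) against DMSO (1 higher, 9 lower; 39 as 14 and 25), 18 for Asbt-/- CME(-) against DMSO (5 and 13; 125 as 50 and 75), and 10 for WT CME(+) against DMSO (23). They were 0 for the Asbt-/- extracts (3) and 0 for tCDCA against Asbt-/- CME(-) (15). Asbt-/- CME(+) against DMSO had 269 higher and 18 lower (182 and 121), and tCDCA against WT CME(-) 40 and 10 (35 and 36). Changes of sign were Slc51a at -0.11 between the Asbt-/- extracts and 0.01 for tCDCA against Asbt-/- CME(-), Slc51b at -0.06 between the CME(-) extracts, 0 between the CME(+) extracts and 0.19 for tCDCA against WT CME(-), and Fabp6 at -0.07 between the CME(+) extracts.

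With no run term, calls were 176 for tCDCA against DMSO (50 higher, 126 lower), 1 between the Asbt-/- extracts, 2, 3, 3 and 3 for WT CME(-), Asbt-/- CME(-), WT CME(+) and Asbt-/- CME(+) against DMSO, and 0 for tCDCA against either CME(-) extract. Lists called were 3 between the WT extracts (8), 6 between the Asbt-/- extracts (10), 1 for the interaction (2), 2 between the CME(-) (6) and 3 between the CME(+) extracts (5), and 5 for tCDCA against Asbt-/- CME(-) (14). Slc51b was at -0.02 between the CME(-) extracts, Fabp6 at 0.3 and 0.05 with WT CME(-) and WT CME(+) against DMSO, and Dcn at 0.37 with Asbt-/- CME(+) against DMSO (-0.64). Fabp6 and Slc51b were both at -0.07 for tCDCA against Asbt-/- CME(-).

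With the compared groups alone, calls were 298 for tCDCA against DMSO, 75 between the Asbt-/- extracts, 2 between the CME(-) extracts, 22, 63 and 474 for WT CME(-), Asbt-/- CME(-) and Asbt-/- CME(+) against DMSO, and 17 and 2 for tCDCA against WT and Asbt-/- CME(-). Slc51a was at 0.01 between the WT extracts. With all 24 libraries they were 418 for tCDCA against DMSO, 1 between the Asbt-/- extracts (none of the 3 genes of the main analysis), 4, 9, 1 and 50 for the extracts against DMSO in the order above, and 39 for tCDCA against WT CME(-). Lists called were then 4 for the interaction, 2 and 8 between the CME(-) and CME(+) extracts, and 7 and 9 for WT CME(-) and WT CME(+) against DMSO (12 and 14). Slc10a2 was at 0.04 between the CME(+) extracts, Fabp6 at 0.2 and 0.05 with the WT extracts against DMSO, and Fabp6 and Slc51b at -0.02 and -0.01 for tCDCA against Asbt-/- CME(-). With DMSO replicate 1 added, calls were 464 for tCDCA, 7, 22, 4 and 74 for the extracts against DMSO, 1 between the Asbt-/- extracts and 45 for tCDCA against WT CME(-), and Fabp6 was at 0.19 with WT CME(-) against DMSO. Without tCDCA replicate 3 and DMSO replicate 3, calls were 324 and Fabp6 was at -0.39. With the rRNA left out Slc51a was at 0 between the WT extracts.

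With no count filter, calls were 17 and 59 between the WT and Asbt-/- extracts, 4 and 2 between the CME(-) and CME(+) extracts, 107, 258, 83 and 476 for the extracts against DMSO, and 196 and 78 for tCDCA against WT and Asbt-/- CME(-). With DESeq2 they were 4 (1 higher, 3 lower) and 54 (26 and 28; 2 and 1 in the main analysis), 117, 272, 95 and 498, and 176 and 68 (38 and 30; 6 and 9). In the second run alone, calls were 1 between the WT extracts, 15, 56 and 14 for WT CME(-), Asbt-/- CME(-) and WT CME(+) against DMSO, and 80 for tCDCA against Asbt-/- CME(-). Lists called were 6 between the Asbt-/- extracts and 3 between the CME(-) extracts. Slc51a was at -0.29 between the Asbt-/- extracts, 0.15 for the interaction and 0.19 for tCDCA against Asbt-/- CME(-), Slc10a2 at 0.21 between the CME(+) extracts and Slc51b at 0.15 for tCDCA against WT CME(-). The fold changes with tCDCA correlated at 0.011 with those between the WT extracts and -0.072 with those between the Asbt-/- extracts. The interaction called 0 genes in every alternative of edgeR and in DESeq2 (491 at an unadjusted p under 0.05).

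With the replicate number as a block, calls were 650 for tCDCA against DMSO, 1 between the Asbt-/- extracts, 28 and 81 for WT CME(-) and Asbt-/- CME(-) against DMSO and 4 for tCDCA against Asbt-/- CME(-). Fabp6 was at 0 between the CME(+) extracts and Slc51b at 0.01 for tCDCA against WT CME(-). With the extract donor as a block in the paired groups alone, 22 and 19 genes were called between the WT and Asbt-/- extracts, no call of a named gene was lost, and Gna11 (-0.74) and Aldh2 (-0.86) gained one between the WT extracts. With an estimated correlation in camera, 4 lists were called for tCDCA against DMSO (13), 3 between the Asbt-/- extracts (10), and 0 in each of the other 10 comparisons.

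Leaving out each library in turn, calls ran from 327 (without DMSO replicate 3) to 812 (without tCDCA replicate 2) for tCDCA against DMSO, and 0 to 1 between the WT extracts. They ran from 1 to 10 between the Asbt-/- extracts, 0 to 1 between the CME(-) and between the CME(+) extracts, 7 to 69, 10 to 170, 5 to 29 and 56 to 401 for the extracts against DMSO, and 30 to 135 and 0 to 58 for tCDCA against WT and Asbt-/- CME(-). Fold changes that crossed 0 were Fabp6 for tCDCA against DMSO (-0.24 to 0.3), WT CME(-) against DMSO (-0.19 to 0.07), and Asbt-/- CME(-) against DMSO (-0.08 to 0.17). Others were Fabp6 for tCDCA against WT CME(-) (-0.19 to 0.33) and Asbt-/- CME(-) (-0.28 to 0.22), and between the CME(+) extracts (-0.08 to 0.1). Slc51a did so between the WT extracts (-0.1 to 0.08), between the Asbt-/- extracts (-0.21 to 0.32), in the interaction (-0.33 to 0.21), between the CME(-) extracts (-0.53 to 0.02) and for tCDCA against Asbt-/- CME(-) (-0.37 to 0.17). Slc51b did so in the interaction (-0.25 to 0.07), between the CME(-) extracts (-0.1 to 0.16), between the CME(+) extracts (-0.01 to 0.28) and for tCDCA against WT CME(-) (-0.14 to 0.11) and Asbt-/- CME(-) (-0.11 to 0.14). Slc10a2 did so in the interaction (-0.33 to 0.19), between the CME(-) extracts (-0.37 to 0.1) and between the CME(+) extracts (-0.24 to 0.13), and Fgf15 between the CME(+) extracts (-0.38 to 0.12).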

Other observations

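No tests in this part were chosen after a result was seen. With Asbt-/- CME(+) against DMSO the cholesterol synthesis genes Acat2 (0.98 ± 0.24) and Dhcr7 (0.84 ± 0.23) rose (2 of 25, 5 adjusted over the list alone, median 0.36), and with WT CME(+) none of the list was called (3 higher adjusted over the list alone, median 0.28). Camera called the list in both, at 0.000148 and 0.000413 (adjusted p = 0.278 and 0.3 with an estimated correlation). Of 18 proliferation genes Mcm2, of the replicative helicase, rose with Asbt-/- CME(+) (0.96 ± 0.26; 4 adjusted over the list alone, median 0.59; camera 2.7e-06, adjusted p = 0.118 with an estimated correlation), and with WT CME(+) the median was 0.4 (none adjusted over the list alone; 0.00117, adjusted p = 0.297 with an estimated correlation). Of the hypoxia and glycolysis genes Car9 rose with both (0.78 ± 0.16 and 0.81 ± 0.17) and Adm with Asbt-/- CME(+) (0.79 ± 0.22; camera 0.00606 and 0.00331, adjusted p = 0.278 and 0.3 with an estimated correlation). The antimicrobial lectin gene Reg3g rose with Asbt-/- CME(+) (1.31 ± 0.24; 1 of 11 called, 5 adjusted over the list alone, median 0.73; camera 0.000149, adjusted p = 0.118 with an estimated correlation).

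PXR and CAR targets had negative medians with tCDCA relative to the CME(-) extracts, and neither result held with an estimated correlation. The median was -0.31 relative to WT CME(-), where Sult1b1 alone was called (-0.66 ± 0.17, with 5 of 16 lower adjusted over the list alone). It was -0.43 relative to Asbt-/- CME(-) (0 called, 1 lower adjusted over the list alone). Camera gave 0.0015 and 0.000608, against adjusted p = 0.13 and 0.129 with an estimated correlation. In the first run, Fabp6 was at 3400 CPM in the removed DMSO replicate 1 and at 5270 to 8260 CPM in the 5 treated libraries. That rests on 1 DMSO library at another DMSO concentration. The second run had no such difference, with a mean of 3750 CPM with DMSO and group means of 3060 to 4170 CPM with the treatments.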
